A study of Mus musculus with 8 samples.

How the data were processed

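Chromatin accessibility was measured by bulk ATAC-seq in hematopoietic stem cells (HSCs) sorted from mouse bone marrow. ATAC-seq uses a transposase that inserts sequencing adapters into open chromatin, so that read counts over a region follow its accessibility. Per the labels' protocols the Omni-ATAC version of the assay was used and libraries were made with a Nextera kit. The titles place 4 libraries in an old group and 4 in a young group, each with replicate numbers 1 to 4. The labels do not say whether replicates came from separate mice, so p-values measure the spread between these libraries, which may be technical. They also do not give the ages or sex of the mice. Age therefore cannot be told apart from any other difference between the 2 groups of libraries.

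The deposited table holds whole-number read counts per peak, not normalized, over 1 peak set shared by the 8 libraries. Trim Galore, FastQC, Bowtie2, SAMtools, Picard, MACS2 and the mouse build mm9 are named, without versions, per the submitters' processing notes. How the shared peak set was merged, which program counted the reads and whether read ends were shifted for the transposase are not given in the sources used here. A peak set made from the same libraries that are compared can favour peaks open in either group. Coordinates are given as in the table, in mm9.

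The table has 126871 peaks, and every column was mapped to a sample by its title. Totals ran from 4200905 to 5129684 counts per library. Peaks were kept with edgeR's filterByExpr by group (minimum count 10, minimum total 15), which left 73164 peaks holding 94.2% of the counts. Values of CPM, which scale counts to a common library size, were computed here from the deposited counts with TMM library scaling, and log2 CPM used a prior count of 2. Old and young were compared with edgeR 4.0.16 (glmQLFit, robust, and glmQLFTest) in R 4.3.3, with group as the only term. A peak was called at a Benjamini-Hochberg adjusted p below 0.05, and log2 fold changes are old minus young. The biological coefficient of variation was 0.114.

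Peaks named by coordinates follow a rule set before the data were examined: in each direction the 5 called peaks with the smallest p whose 4 old libraries all lay on one side of the 4 young libraries in CPM. Windows and runs of peaks that are named were chosen after their values were seen, windows by smallest p among those with at least 3 called peaks and runs by the number of called peaks. An array on chromosome 8 was picked for its even spacing and a cluster on the X chromosome for its number of lower peaks. Library totals, shares of counts and the spread within groups were compared with two-sided exact permutation tests over the 70 assignments of 8 libraries to 2 groups of 4, whose smallest p is 0.0286. The directions of adjacent called peaks were compared with 10000 permutations. Counts were also summed over windows of 100000 bases and tested in the same way, in place of a gene-level test. Peaks were split into quintiles by mean CPM, by width and by the number of other deposited peaks within 250000 bases. The last split, the windows and the count of changes over 4-fold were added after the data were examined. Sets of peaks were tested with limma 3.58.1, with camera at a preset correlation of 0.01 and again with an estimated one, and with fry.

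The test was checked on simulated counts with a mean per peak pooled over the 8 libraries, their library sizes and a dispersion per peak. Peaks were drawn independently, so correlation between neighbouring peaks and an intermediate library were not simulated. Of 50 peaks changed at each size, 14% were called at 1.5-fold, 32% at 2-fold, 80% at 3-fold and 84% at 4-fold, with 11 false calls among 70025 peaks. With no change simulated, 0 of 70011 peaks and 1 of 15562 windows were called. Small changes of single peaks were therefore often missed in this simulation. Few peaks changed in it, which makes the adjusted p stricter, so these rates do not carry over to the real comparison.

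Alternatives were DESeq2 1.42.0 size factors, total count scaling, loess offsets, no count filter, a mean count of at least 50, DESeq2's own test, limma voom, an adjusted p below 0.01, a minimum fold of 1.5 with glmTreat, a replicate block, autosomes only and each library left out in turn. Planned comparisons of promoter and distal peaks, of gene lists (including markers of other cell types the gate could hold), of genes and of sequence motifs were not analysed here, because no annotation or sequence of the mm9 build was used.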

Results

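The design asked how chromatin accessibility in HSCs differs between young and old mice of the C57BL/6 strain. HSCs were sorted as LSK CD150+ CD48- cells, that is lineage-negative marrow cells with Sca-1 and Kit on their surface, further gated on a pair of SLAM-family markers. There were 4 old and 4 young libraries. Total counts were 4767451 ± 434819 in old and 4658213 ± 354566 in young libraries (SD, n = 4 each; two-sided exact permutation p = 0.686).

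Libraries separated by group along the first principal component, which held 53.7% of the variance. The young libraries lay between 52.9 and 99.0, and old replicates 1 to 3 between -111 and -96.6. Old replicate 4 lay at -13.7, between these sets. Pearson correlations of log2 CPM across tested peaks were 0.913 to 0.958 between old libraries, 0.933 to 0.940 between young libraries and 0.823 to 0.925 between the groups. Old replicate 4 had a mean correlation of 0.919 with the other old libraries and 0.907 with the young ones. The library closest to it was young replicate 2 (r = 0.9253), ahead of old replicate 1 (r = 0.9241). The mean distance within groups (1 minus r) was 0.0630 in old and 0.0638 in young libraries (two-sided exact permutation p = 0.886). The permuted sets mix old and young libraries, so the age difference adds to their distances and this test has little power to detect a difference in spread. Without old replicate 4 the difference, old minus young, moved from -0.000797 to -0.0198 (two-sided exact permutation p = 0.286), and r was then 0.952 to 0.958 between old libraries. No pair of libraries agreed within sampling noise: chi-square per peak was at least 1.20 in every pair.

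**Figure D1:**
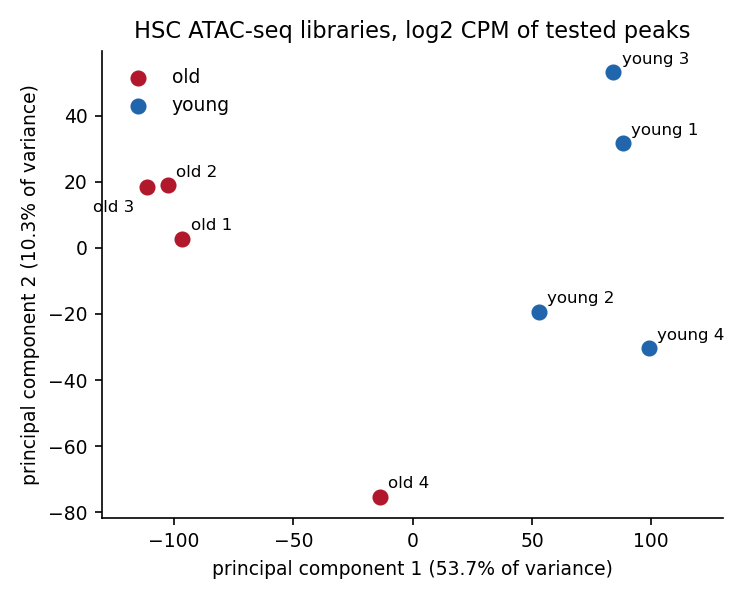
First and second principal components of log2 CPM over tested peaks, 1 point per library, old in red and young in blue. The young libraries lie at 52.9 or above on the first component, old replicates 1 to 3 at -96.6 or below, and old replicate 4 at -13.7.

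Accessibility differed between the old and young libraries at 1 in 5 tested peaks. In old HSCs 7352 peaks were higher and 7634 lower, together 20.5% of the 73164 tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05). All 4 old libraries lay on one side of all 4 young libraries at 21.1% of all tested peaks, where chance gives 2.86%. The share was 77.2% among the called peaks, which were selected for such a difference, so that chance rate does not apply to them. The median size of change was 0.88 on the log2 scale for peaks that rose and 0.98 for peaks that fell. With TMM scaling, peaks that rose were wider (median 736 against 605 bases) and stronger (median mean CPM 9.04 against 6.62). Without old replicate 4, 10997 peaks were higher and 11802 lower.

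Among peaks that opened in old HSCs, the smallest p belonged to a peak on chromosome 7 from 6680473 to 6681765 (mm9), close to closed in young cells. Its level was 44.9 ± 7.61 CPM in old and 0.383 ± 0.274 CPM in young libraries (SD, n = 4 each), from 794 and 7 counts in all. The log2 fold change was 6.72 ± 0.28 (SE; edgeR adjusted p = 3.55e-12). The peak on chromosome 2 from 107071603 to 107072306 had 33.0 ± 1.73 CPM in old against 0.648 ± 0.449 in young libraries, a log2 fold change of 5.67 ± 0.25. On chromosome 15, the peak from 91881356 to 91882503 had 20.6 ± 4.31 against 0.411 ± 0.256 CPM. The peak on chromosome 11 from 65981256 to 65982269 rose from 1.44 ± 0.580 CPM in young to 20.1 ± 1.38 in old libraries. The peak on chromosome 12 from 47919316 to 47921076 was already open in young libraries, at 10.9 ± 0.697 CPM, and rose to 46.9 ± 6.11. Each of these 5 peaks had at most 7 other peaks within 250000 bases, where the median tested peak had 46.

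Among peaks that closed, the peak on chromosome 16 from 14088242 to 14088844 fell from 12.5 ± 3.15 CPM in young to 1.10 ± 0.312 in old libraries, a log2 fold change of -3.45 ± 0.29 (SE; edgeR adjusted p = 1.76e-07). The peak on chromosome 7 from 50788261 to 50789032 fell from 22.2 ± 4.22 to 4.52 ± 1.59 CPM. On chromosome 11, the peak from 72565252 to 72565899 fell from 9.81 ± 1.36 to 1.54 ± 0.418 CPM. The peak on chromosome 2 from 28651852 to 28652242 fell from 11.9 ± 3.20 to 1.21 ± 0.724 CPM, and young replicate 2 was the lowest young library there at 7.16 CPM. The peak on chromosome 13 from 102078625 to 102079100 fell from 10.7 ± 1.22 to 1.71 ± 0.678 CPM. Neighbouring peaks numbered 11 at the last of these and 40 to 50 at the other 4. What the annotation holds at these positions was not analysed here.

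**Figure D2:**
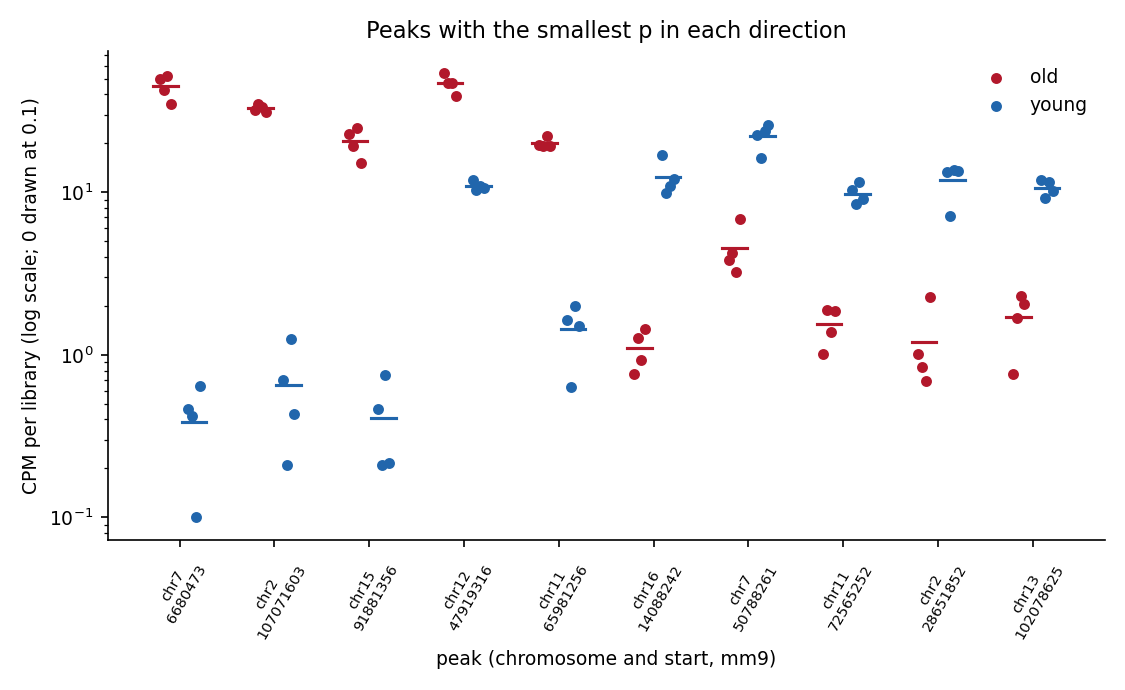
CPM in each library on a log axis at the 5 peaks with the smallest p in each direction, with horizontal bars at group means, old in red and young in blue. Old libraries lie above all young libraries at the 5 peaks on the left and below them at the 5 on the right, and a library with 0 counts is drawn at the axis floor.

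With all 8 libraries, fitted changes over 4-fold were more often gains than losses, at 690 peaks higher and 407 lower. Over 8-fold 87.1% were gains and over 16-fold 96.3%. Without old replicate 4 the counts over 4-fold turned to 1096 higher and 1538 lower, and gains made up 52.2% over 8-fold and 65.5% over 16-fold. With each other library left out in turn, gains made up 76.9% to 90.9% over 8-fold. Among called peaks changed over 4-fold, gains made up 84.7% of those with at most 29 other peaks within 250000 bases and 45.4% of those elsewhere. With each library left out in turn these shares were 72.5% to 89.4% and 26.1% to 54.0%, both lowest without old replicate 4. Without young replicate 2 the counts over 4-fold were 1160 and 692. Peaks near closed in young libraries (mean CPM under 1) and at 5 or more in old ones numbered 153, against 41 near closed in old libraries. Without old replicate 4 these were 214 and 159, and without young replicate 2 they were 210 and 73.

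**Figure D3:**
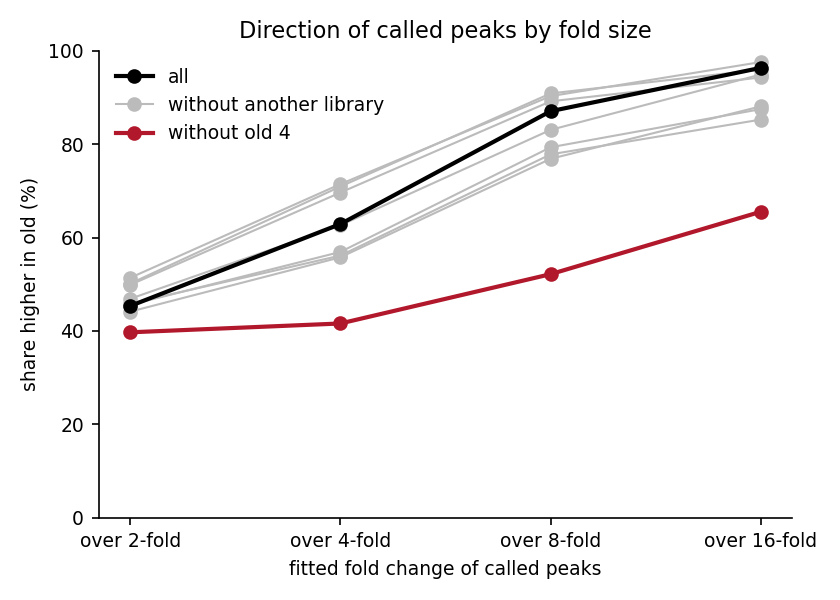
Share of called peaks that were higher in old libraries (vertical axis, percent) among fitted changes over 2-, 4-, 8- and 16-fold (horizontal axis), with all 8 libraries in black, without old replicate 4 in red and without each other library in grey. Over 4-fold the share is 62.9% with all libraries and 41.6% without old replicate 4.

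Called peaks in regions with few other peaks were mostly gains, though 24.1% of the tested peaks there were called at all. In the quintile of tested peaks with at most 29 others within 250000 bases, 2476 were higher and 1240 lower in old HSCs, so that 66.6% of called peaks were gains. Elsewhere 4876 were higher and 6394 lower, or 43.3% gains. The share of gains was 63.4% to 78.5% in the peak-poor quintile and 31.6% to 61.4% elsewhere across quintiles of peak strength, and in each of these it was higher in the peak-poor quintile. As a set, peak-poor peaks had a median log2 fold change of 0.11 (limma camera p = 0.0027 with the preset correlation, p = 0.0609 with an estimated correlation, and fry p = 0.00593), so the set's call was lost with the estimated correlation. The call was also lost when a per-library trend with the number of neighbouring peaks was removed (limma camera with the preset correlation, p = 0.954). There were then 1892 peaks higher and 1649 lower in the peak-poor quintile, so that gains made up 53.4% against 50.2% elsewhere. Peak-poor neighbourhoods held 19.8 ± 0.711% of counts in old and 18.5 ± 0.266% in young libraries (SD, n = 4 each), which did not pass a two-sided exact permutation test (p = 0.0571). Old replicate 4, at 18.7%, lay within the young range.

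**Figure D4:**
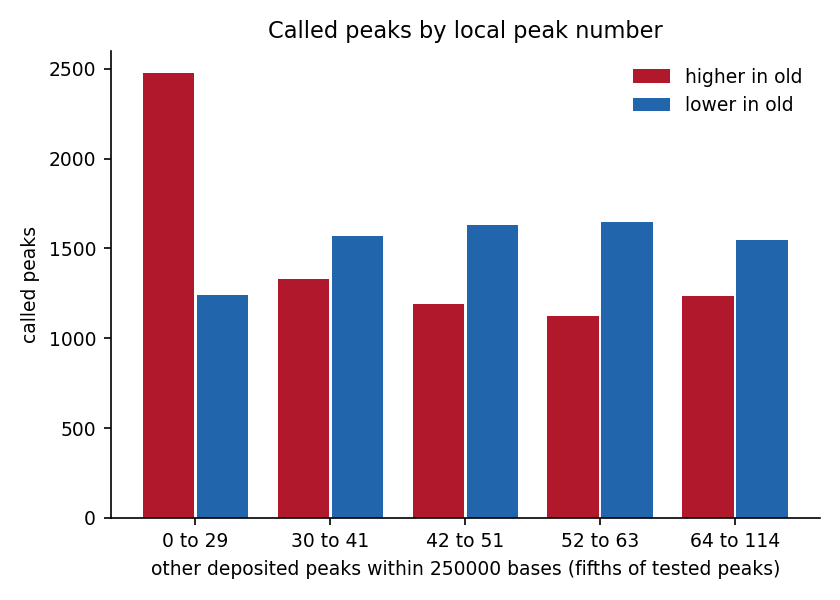
Called peaks higher (red) and lower (blue) in old libraries, as counts on the vertical axis, by quintiles of tested peaks ordered by the number of other deposited peaks within 250000 bases. Gains outnumber losses in the quintile with 0 to 29 neighbours, 2476 to 1240, and losses outnumber gains in the other 4 quintiles.

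With TMM scaling, called peaks were more often gains among strong and wide peaks than among weak and narrow ones. In the strongest quintile by mean CPM 2090 peaks were higher and 1152 lower, against 1030 and 1433 in the weakest. In the widest quintile, 995 bases or more, 2171 were higher and 895 lower. These splits moved with the scaling. After a loess against peak strength, which removes a trend with strength by construction, gains made up 48.5% of called peaks in the strongest quintile. They made up 59.6% in the widest quintile and 48.9% of all called peaks. With peaks of a mean count of at least 50 scaled on their own, they made up 50.1% of the strongest and 56.6% of the widest. Of all peaks called with that filter they made up 45.9%. Under both alternatives the share among the widest peaks stayed above that of all called peaks. The widest quintile then held 12492 tested peaks rather than 14625, so its share may have moved with the filter as well as the scaling. The top 1% of peaks took 12.4 ± 0.225% of counts in old and 11.9 ± 0.171% in young libraries (SD, n = 4 each; two-sided exact permutation p = 0.0286, the smallest possible).

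Peaks on the X chromosome changed less often than those on autosomes. Of 1566 tested X peaks 103 were higher and 88 lower, which is 12.2% against 20.7% on autosomes. Among 10000 random sets of autosomal peaks matched on abundance the lowest share was 16.7%. The share was lower on X than on autosomes also with each library left out in turn, from 7.28% against 13.9% without old replicate 2 to 19.8% against 30.2% without old replicate 4. The share of counts per chromosome in old libraries was 0.983 to 1.02 of that in young libraries for autosomes and X. Chromosomes 4, 5, 7, 8, 10, 13 and 17 reached an exact permutation p of 0.0286, the smallest possible. On each of these all old libraries lay on one side of all young ones. After Benjamini-Hochberg adjustment over 21 chromosomes this p was 0.0857, so none passed. With that smallest p, many more chromosomes would have had to reach it for any to pass, so the adjusted test could hardly show a difference.

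Changes ran together along chromosomes. Of adjacent called peaks 60.8% changed in the same direction, against 50.02% on average and 51.5% at most in 10000 permutations of the directions (p = 1e-04, the smallest they can give). The permutations treat called peaks as independent and keep the libraries fixed, so this p does not measure the spread between libraries. It cannot tell an age difference shared by neighbouring peaks from library noise that they share. The share was 84.8% for pairs up to 1000 bases apart, where the mix of gains and losses alone gives 52.5%. Beyond 250000 bases it was 56.4% against 52.2%, with 907 pairs both higher and 416 both lower.

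**Figure D5:**
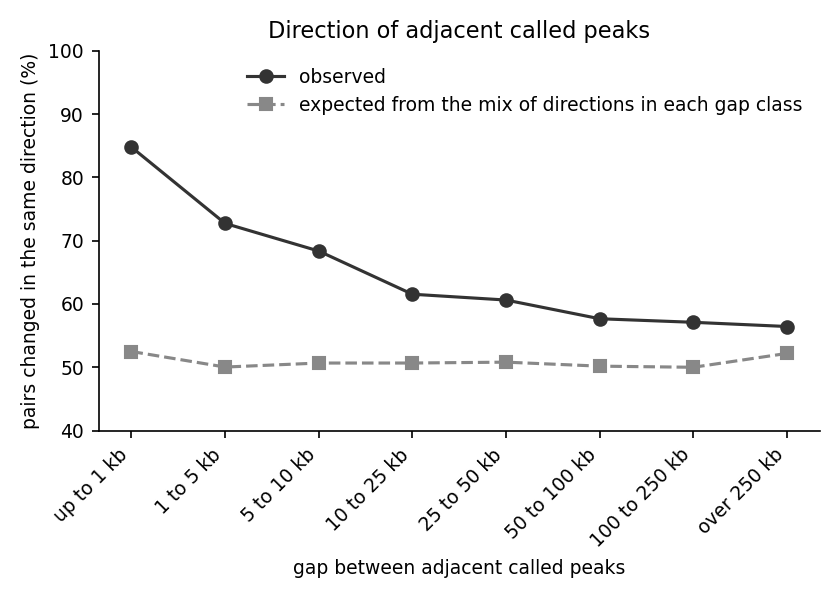
Share of adjacent called peaks that changed in the same direction (vertical axis, percent, starting at 40) by the gap between them (horizontal axis), with the share expected from the mix of directions in each gap class as a dashed line. The share falls from 84.8% up to 1000 bases to 56.4% over 250000 bases, where the expected share is 52.2%.

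Of 16764 tested windows of 100000 bases, 2418 were higher and 2466 lower in old HSCs (edgeR adjusted p below 0.05). Without old replicate 2 the number lower was 1581. The window on chromosome 7 from 6600001 to 6700000, which holds the peak with the smallest p, rose from 6.57 ± 0.775 to 71.1 ± 11.7 CPM (SD, n = 4 each). The window on chromosome 13 from 72700001 to 72800000 rose from 28.4 ± 3.03 to 77.3 ± 5.63 CPM, with 5 of 5 tested peaks called higher. On chromosome 3, the window from 57300001 to 57400000 rose from 68.8 ± 5.21 to 136 ± 3.45 CPM, and old replicate 4 had 137 CPM there, at the level of the other old libraries. Among windows that closed, the one on chromosome 8 from 10500001 to 10600000 fell from 63.6 ± 5.24 to 31.6 ± 1.03 CPM. The window on chromosome 17 from 88500001 to 88600000 fell from 52.1 ± 6.43 to 21.3 ± 3.23 CPM.

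The longest run of called peaks that all rose, with called peaks at most 100000 bases apart, lay on chromosome 8 from 126067530 to 126274608 and held 40 called peaks. Most of it was an array of 51 peaks between 126062386 and 126147993, set a median of 1698 bases apart. Of these 38 were higher and 0 lower, and their summed level was 1369 ± 122 CPM in old and 966 ± 184 CPM in young libraries (SD, n = 4 each; two-sided exact permutation p = 0.0286). Levels of the other runs are sums over all tested peaks in their span, called or not. On chromosome 5, a run of 11 called peaks from 38090923 to 38293560 lay in a span of 14 tested peaks, whose sum was 44.0 ± 4.87 CPM in young and 113 ± 13.9 CPM in old libraries, a ratio of 2.57. The longest run that fell held 20 called peaks on chromosome 5 from 100590981 to 101073283, among 44 tested peaks whose sum was 448 ± 52.8 CPM in old against 604 ± 24.3 in young libraries. On chromosome 12, a run of 19 called peaks from 116261853 to 116861743 lay among 28 tested peaks, whose sum in old was 0.566 of that in young libraries. The 5 tested peaks within 100000 bases of it had a median log2 fold change of -0.55, with 0 called. A run of 14 called lower peaks on chromosome 2 from 166087060 to 166580642 lay among 56 tested peaks, whose median log2 fold change was -0.16, or -0.27 without old replicate 4. The peaks flanking it had a median of -0.15 with all libraries. A cluster of 12 peaks on the X chromosome from 72974936 to 73004069 fell as a whole, from 310 ± 34.5 to 138 ± 44.1 CPM, with all 12 called lower. The runs were picked for their number of called peaks, and the X cluster because its window held the most peaks called lower, so their tests describe regions already chosen as changed.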

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

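Before the result was seen, criteria were set for the tests of a mixture and of enrichment in old replicate 4. The tests of a wrong label, the comparison with mixtures made from the counts, the split of the mixture into reads and cells, and the choice of a library to examine came after. In 116 groups of 4 values screened for a library far from the other 3, 9 stood out, where chance gives about 1 in 20, or 5.8. Of these 9, 7 were old replicate 4.

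Old replicate 4 stood apart from the other old libraries in its mean correlation with its own group (0.919, the others 0.941 to 0.944) and on the first principal component (-13.7). It also stood apart in its share of counts in peak-poor neighbourhoods (18.7%, the others 20.01% to 20.2%). Its shares of counts were low on chromosome 3 (4.75%) and chromosome 18 (2.93%), and high on chromosome 11 (8.14%) and chromosome 17 (5.28%). Old replicate 3 was highest at the peak on chromosome 11 from 65981256 to 65982269, with 22.1 CPM against 19.2 to 19.6 in the others. Young replicate 2 was lowest at the peak on chromosome 2 from 28651852 to 28652242, with 7.16 CPM against 13.3 to 13.8.

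At peaks called without it, old replicate 4 sat at 0.472 ± 0.0040 (jackknife SE over chromosomes) on a scale from 0 at the young mean to 1 at the mean of the other old libraries. It sat at 0.463 for peaks that rose and 0.482 for peaks that fell, while old replicates 1 to 3 sat at 0.996 to 1.13 and the young libraries at -0.0236 to 0.309. At 216 peaks chosen without it as near closed in young and open in old libraries, it lay above all young libraries at 98.1%, where young libraries treated alike did so against the others at 27.9% to 50.5%. At 164 peaks near closed in old and open in young libraries it lay below all young libraries at 67.7%, within the 11.1% to 76.7% of young libraries treated alike. The opened peaks and the position of 0.472 argue against a young library labelled old. After a loess against peak strength the position was 0.474, which met the criterion set beforehand against lower enrichment. That loess depends only on average strength. It cannot undo a pull of opened and closed peaks of like strength towards each other, so lower enrichment stays open. Reads of young type mixed in at one proportion stay open. The mean squared residual of old replicate 4 around one position was 1.60, against 1.31 for the next old library. In panels without the libraries used for mixing it was 1.66 to 1.82. For 12 mixtures of the reads of an old and a young library it was 0.792 to 0.933. These values argue only against the pairs mixed here as the source. Pooling an old and a young library averages out what is particular to each, which lowers the residual. Reads from a library outside these pairs could not be tried. Young cells mixed in before library preparation stay open too, although 1.60 met the criterion set beforehand against them. Young replicate 4, which is not intermediate, had 1.62, so a single preparation can deviate as much. A biological difference between old animals was not tested.

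An intermediate library limits fitted losses more than gains, since a peak closed in 3 old libraries and at 0.472 of the way in the fourth keeps a sizeable mean. This may account for part of the excess of gains among changes over 4-fold, as it turned to 1096 higher and 1538 lower without old replicate 4, though in peak-poor neighbourhoods 72.5% of such changes were still gains.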

How the results depend on the processing

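With a mean count of at least 50, which tests fewer peaks, 2377 peaks were higher and 2800 lower in old, with 45 and 8 over 4-fold and 642 and 354 in peak-poor neighbourhoods. With no count filter, which tests more, 2345 and 1899 changed over 4-fold and 4091 and 1880 were called in peak-poor neighbourhoods. At an adjusted p below 0.01 the counts were 3694 and 3678, and 1404 and 638 in peak-poor neighbourhoods. With a minimum fold of 1.5 they were 1685 and 1510, and 851 and 302. Windows of 250000 bases, which are fewer, gave 1361 and 1286. The camera p of peak-poor neighbourhoods was 0.0609 with an estimated correlation and 0.954 with neighbour-number offsets, which remove that trend by construction. DESeq2 called 4993 and 5215 peaks. Leaving out each library in turn gave 5184 to 10997 peaks higher and 5199 to 11802 lower. It gave 653 to 1160 and 376 to 1538 over 4-fold, 1784 to 3608 and 946 to 1789 in peak-poor neighbourhoods (camera p 0.000595 to 0.0115), and 1869 to 3075 and 1581 to 3231 windows. The share of adjacent peaks in the same direction was 61.1% to 62.5%, and the difference in spread -0.0198 to 0.00442. Losses outnumbered gains over 4-fold when old replicate 4 was left out, and in no other such fit. Another 170 values tied to comparisons and all 450 of named peaks, windows and runs kept direction and side of the threshold, or stayed within 1.5 times for counts. Named peaks and windows were chosen for small p in the same counts, so little else could come of refitting them. Most named peaks were not tested with a mean count of at least 50 and have no value there. The difference in spread had the opposite sign in 9 of its 18 alternatives. The replicate block gave 8111 higher and 8647 lower. Whether the numbers pair the libraries stays open. Deviations of same-numbered libraries correlated at -0.014, 0.0736, 0.0495 and 0.179, the last being the highest of any old and young pair. Of the 8 libraries, 4 correlated best with their own number in the other group. Settings for windows, the strongest and widest quintiles, peak-poor neighbourhoods and changes over 4-fold, and neighbour-number offsets, were chosen after seeing the data. GC trends, promoter distances, gene lists and motifs were not run. In the simulation, in which few peaks changed, changes up to 2-fold at single peaks were mostly missed. The adjusted p is stricter when few peaks change, so these rates do not carry over to the real comparison.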

Other observations

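Regions with several peaks called in one direction were found beyond the longest ones. Of the tested windows of 100000 bases, 38 held at least 5 peaks called higher and 50 at least 5 called lower. How many such windows chance would give, from the number of peaks per window, was not tested. Among the windows that were themselves called, 335 held peaks called in both directions. On chromosome 18, the window from 81700001 to 81800000 fell from 66.9 ± 3.09 to 29.2 ± 5.90 CPM (SD, n = 4 each). On chromosome 4, the window from 117100001 to 117200000 fell from 193 ± 12.5 to 135 ± 6.99 CPM, with 8 of 12 tested peaks called lower. On chromosome 7, the window from 77400001 to 77500000 rose from 20.5 ± 1.35 to 57.0 ± 3.86 CPM. On chromosome 1, a run of 12 called higher peaks from 75313273 to 75556641 lay among 28 tested peaks, whose sum was 410 ± 13.6 CPM in young and 519 ± 14.7 CPM in old libraries. Of the 153 peaks near closed in young and open in old libraries, 103 (67.3%) lay in the peak-poor quintile.

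Criteria for the splits by called peaks and windows and for the large changes below were set before those results were seen. The split test of the peak-poor shift, and the tests of the peak-strength trend, of smaller changes and of the clustered peaks were chosen after. Of the 35 splits of the 8 libraries, 1, the real split, called as many as 14986 peaks, and the highest of the others called 1. For windows the real count was 4884 and the highest other 0, again with 1 of 35 splits as large. The other splits mix old and young libraries, so age adds to their spread and lowers their counts. The test can give no stronger result than 1 of 35. Chance as the source of the old and young difference is therefore argued against at that level, and not excluded.

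The excess of gains in peak-poor neighbourhoods is a hypothesis from these data, and chance is not excluded for it. The median log2 fold change of peak-poor peaks differed from that of the others by 0.12, and 2 of the 35 splits gave as much, the other one (0.13) having young replicate 2 in place of old replicate 4. A trend with peak strength is argued against, since 67.4% of called peaks there were gains after a loess against strength and 42.7% elsewhere. After removal of a smooth trend with neighbour number, 78.7% of changes over 4-fold were gains in peak-poor neighbourhoods and 48.7% elsewhere, which met the 65% set beforehand. Without old replicate 4 the shares were 62.6% and 28.9%, which falls short of it. Before removal the peak-poor shares were 84.7% with all 8 libraries and 72.5% without old replicate 4, so removal lowered both. As the criterion was met only with old replicate 4 included, such a trend stays open for changes over 4-fold. For smaller changes it cannot be told apart from an age effect, as the share fell to 49.8% against 50.3% by construction of the correction. GC content, which may follow peak density, was not analysed here, and opening of peak-poor regions with age stays open.

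The 51 peaks of the chromosome 8 array deviated together within groups (mean r = 0.722, with 0 of 1000 random runs of as many neighbouring peaks as high). The 12 peaks of the X chromosome cluster did so too (mean r = 0.81, with 1 of 1000 as high). Reads shared between near-identical repeat copies, or a copy number particular to each animal, may give such values, and so may joint regulation, which was not tested. Peaks within 100000 bases of the array had a median log2 fold change of 0.15 against 0.50 inside it, which leaves a change in copy number and one in accessibility per copy both open.

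The Y chromosome held 24 to 49 counts per library.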
